A study of Mus musculus with 19 samples.

How the data were processed

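The series held bulk RNA sequencing of CD8 and CD4 T cells sorted from liver metastases of mice with floxed Tet2. Per the labels' protocols, tumours were digested with collagenase A and DNase I, leukocytes were enriched on a density gradient and with CD45 beads, and T cells were sorted on CD45, CD3ε, CD4 and CD8α. RNA was made into libraries with a SMARTer Stranded Total RNA Pico kit and sequenced as read pairs on a HiSeq X, per the labels' protocols. Total RNA kits of this kind remove ribosomal fragments after amplification and carry no molecular identifiers in the values used here, so intervals and floors cover counting error only. Groups and replicate numbers came from the sample labels, which give every genotype its own animals, so that replicates were separate animals.

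The authors deposited 1 table per cell type, with 25639 genes in each. The CD4 table held counts of reads per gene and RPKM values for every library, per the file headers. The CD8 table held RPKM values only, per the file headers. RPKM was made by the authors as reads per kilobase of gene, scaled to the reads of the library. Both tables also held the authors' log2 fold change against Tet2fl/fl and the authors' p-value and false discovery rate, which were copied to set beside the calls made here and entered no test. The builds GRCm38 and mm10 are named in the submitters' processing notes, and the aligner, the counter and their versions are not given in the sources used here. Of the gene IDs, 25582 matched the GRCm38 annotation used for comparison, and 25081 had the same length there but only 551 had the same chromosome, start and end, with a median shift of 136536 bases. Tet2 lay at 133169440 to 133250900 of chromosome 3 in the table and at 133463679 to 133545139 in the GRCm38 annotation. The coordinates printed in the results are therefore those of the tables, whose build is not given in the sources used here. Of the per-sample columns, 28 (counts or RPKM of the 19 libraries) were read and 18 others were not used.

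CD4 counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), scaled with TMM factors and tested with the quasi-likelihood test (robust fit) and Benjamini-Hochberg adjustment at 0.05, with all 9 CD4 libraries in 1 fit. CPM values were made from the counts with TMM factors. The plan was the same test in CD8 cells, but the deposited CD8 values were RPKM, so the planned fallback for RPKM was used there: limma 3.58.1 with a trend on log2(RPKM + 1), over genes of at least 1 RPKM in at least 3 libraries, with all 10 CD8 libraries in 1 fit. The interaction of genotype and cell type was tested in the same way on log2(RPKM + 1) of all 19 libraries, although the authors had normalized the tables separately. RPKM times a gene length implied by the counts and RPKM of the CD4 table gave whole reads: of 134905 CD8 values above 0, 100% lay within 0.01 of a whole number. The length was implied for 20159 genes, including 10212 of the 10224 tested in CD8 cells, while 1571 genes above 0 RPKM in CD8 cells had none. These recovered reads were used for depth and as alternatives. Most low counts were even (13.1% to 30.7% of counts from 1 to 20 were odd in 18 libraries), as when each read pair adds 2 reads, but 50.6% were odd in CD8 Vav1CreTet2KO replicate 1, whose total of 12568865 may therefore be in another unit than the rest.

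The rule for named genes took Tet2, up to 4 called members of each list, and up to 3 members by smallest p of each list that passed and of the inhibitory receptor, exhaustion, naive and memory, and cytotoxic lists. It then took the called genes of largest change with a mean of at least 1 on the log2 scale and groups that did not overlap, up to about 30 per comparison, leaving out unnamed gene models, pseudogenes and receptor segments. Between the knockouts and in the interaction it took fewer. The design, the 37 gene lists, the rule and the settings to be varied were fixed before the data were examined. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, with the same test at an estimated correlation and with limma's fry beside it, adjusted over the lists of a comparison. Camera compares a list with the other genes, while fry asks whether its genes move, on balance, one way.

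Other settings fixed at that point were a pseudocount of 0.1, no filter, DESeq2 1.42.0 and its size factors (RLE), voom with quality weights, only the compared groups in the fit, a block for replicate number or animal, several gene classes left out and each replicate left out. Added after seeing the data were count tests on recovered reads, RPKM divided by size factors, CD8 cells without both Cd4CreTet2KO libraries that held macrophage markers, and dendritic cell genes left out. The animal numbers in the labels tie CD8 and CD4 libraries together: the 8 pairs from the same animal had correlations of deviations from -0.06 to 0.33 across genes (median 0.125, 4 of 8 over 0.1).

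Every test was tried on data simulated from the real means and depths, with 200 genes changed. For CD8 Vav1CreTet2KO against Tet2fl/fl (10155 genes), 1.5%, 23.9% and 51.5% of genes changed 2-fold, 4-fold and 8-fold were recovered, with 8 false calls among 59. For CD8 Cd4CreTet2KO (10177 genes) the shares were 3%, 19.4% and 43.9% (8 false of 52), and between the knockouts in CD8 cells (10185 genes) 4.5%, 31.3% and 53% (6 false of 65). For CD4 Vav1CreTet2KO (12960 genes) they were 1.5%, 13.4% and 43.9% (3 false of 42), for CD4 Cd4CreTet2KO (12984 genes) 3%, 16.4% and 36.4% (1 false of 38), and between the knockouts in CD4 cells (12945 genes) 1.5%, 17.9% and 33.3% (6 false of 41). For the interaction they were 0%, 3% and 13.6% for Vav1CreTet2KO (10950 genes, 0 false of 11) and 0%, 6% and 21.2% for Cd4CreTet2KO (10978 genes, 0 false of 18). No simulated gene was called in the wrong direction, and false calls exceeded 5% of calls in 5 of the 8 simulations. A simulated list of 15 genes raised 2-fold was found in both cell types, with 0 false lists. The simulated genes were drawn independently of each other. The simulation therefore does not show how often lists of correlated genes pass falsely, and a wrong split of the real libraries gave up to 18 lists.

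Same-group libraries correlated across genes at 0.828 to 0.952 in CD8 and 0.73 to 0.95 in CD4 cells, and sums of RPKM ranged from 124408 to 251038 over the CD8 libraries. No library was left out of a main result.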

Results

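Gene expression was measured by RNA sequencing in T cells that had infiltrated liver metastases of mice. The metastases grew for 30 days after colorectal cancer cells carrying a Venus marker were injected into the spleen. Cells were sorted on CD45, CD3ε, CD4 and CD8α, so that CD8 T cells, which kill target cells, and CD4 T cells, which hold helper and regulatory cells, were sequenced as separate libraries. Tet2, the targeted gene, encodes an enzyme that oxidises methylated cytosine in DNA. The mice carried floxed Tet2 without Cre (Tet2fl/fl, the control). Others carried it with a Cre active across blood cells (Vav1CreTet2KO) or with a Cre active in T cells (Cd4CreTet2KO). The CD8 libraries numbered 3 for Tet2fl/fl, 3 for Vav1CreTet2KO and 4 for Cd4CreTet2KO, and the CD4 libraries numbered 3 per genotype. The 19 libraries came from 11 animals, of which 8 gave both cell types. The title of the series places the comparison in the setting of TET2-mutant clonal hematopoiesis, T cell exhaustion and metastasis.

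Total reads on genes ranged from 707866 to 17575534 in CD4 libraries and from 8189300 to 20327809 in CD8 libraries. The CD8 table held RPKM (reads per kilobase of gene, scaled to library size), so its totals are those of reads recovered from the RPKM values. The shallowest library, CD4 Vav1CreTet2KO replicate 1, had reads on 7761 genes, and its median correlation with the other CD4 libraries was 0.722 across genes. Transcripts of heat shock genes, which encode chaperones induced by stress, took 2.52% ± 0.372 (SD, n = 3) of reads on genes in CD8 Tet2fl/fl libraries. They took 1.29% ± 0.243 (n = 3) in CD8 Vav1CreTet2KO and 1.30% ± 0.166 (n = 4) in CD8 Cd4CreTet2KO. In CD4 cells the shares were 2.90% ± 0.570, 1.19% ± 0.264 and 1.23% ± 0.0907 (n = 3 each). Ribosomal protein transcripts took 4.85% ± 0.242, 8.18% ± 2.86 and 5.95% ± 1.16 in CD8 cells of the same genotypes. They took 4.97% ± 0.898, 8.08% ± 1.48 and 4.19% ± 0.974 in CD4 cells. The macrophage gene Lyz2, which encodes lysozyme, stood at 172 and 88.2 RPKM in CD8 Cd4CreTet2KO replicates 1 and 2. It stood at no more than 9.33 RPKM in the other CD8 libraries. Csf1r, the receptor of the macrophage growth factor, stood at 13.2 and 9.97 RPKM in these libraries. Cd3e, a chain of the T cell receptor complex, stood at 298, 202 and 234 RPKM in CD8 Tet2fl/fl libraries. It stood at 161, 200 and 148 RPKM in CD8 Vav1CreTet2KO and at 131, 131, 180 and 173 RPKM in CD8 Cd4CreTet2KO. Every knockout library thus lay below every control.

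**Figure D1:**
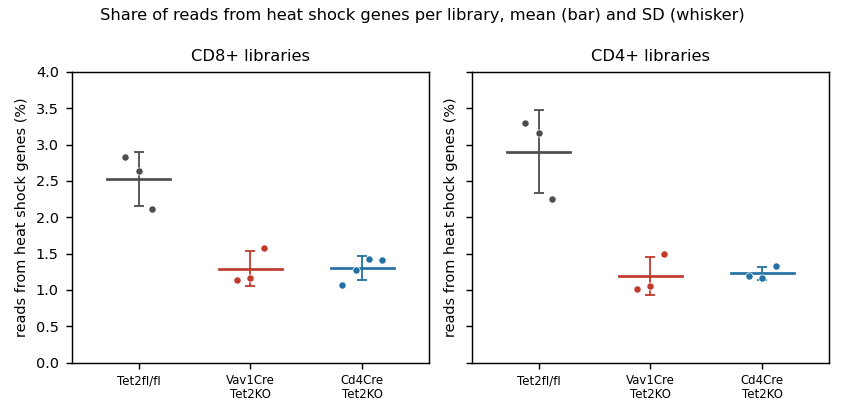
Share of reads on genes taken by heat shock genes (y axis, percent) for each genotype of CD8 and CD4 cells (x axis). Points are libraries, bars are means and whiskers are SDs, and the Tet2fl/fl means of 2.52% and 2.90% lie above the knockout means of 1.19% to 1.30%.

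Tet2 (ENSMUSG00000040943, chromosome 3, 133169440 to 133250900 as the table gives it) was measured in every library. In CD8 cells its level was 7.65, 8.06 and 6.57 RPKM in Tet2fl/fl, 6.28, 5.57 and 2.93 RPKM in Vav1CreTet2KO and 7.57, 4.40, 3.01 and 5.02 RPKM in Cd4CreTet2KO. In CD4 cells it was 4.23, 7.02 and 3.87 RPKM in Tet2fl/fl, 4.31, 5.65 and 2.77 RPKM in Vav1CreTet2KO and 4.53, 7.28 and 4.80 RPKM in Cd4CreTet2KO. The log2 fold change of Tet2 against Tet2fl/fl in CD8 cells was -0.55 (SE 0.33, limma adjusted p = 0.405) for Vav1CreTet2KO and -0.54 (SE 0.31, limma adjusted p = 0.523) for Cd4CreTet2KO. In CD4 cells it was -0.16 (SE 0.38, edgeR adjusted p = 0.911) and 0.25 (SE 0.38, edgeR adjusted p = 0.9998). Between the knockouts it was -0.01 in CD8 cells (limma adjusted p = 0.993) and -0.41 in CD4 cells (edgeR adjusted p = 0.774). The CD4 signs against Tet2fl/fl rested on single libraries, while the sign between the CD4 knockouts did not change without any single library. The Vav1CreTet2KO value was 0.154 without Tet2fl/fl replicate 2 and 0.035 without Vav1CreTet2KO replicate 3. The Cd4CreTet2KO value was -0.031 without Cd4CreTet2KO replicate 2. In CD8 cells the difference between the knockouts was 0.176 and 0.006 without Cd4CreTet2KO replicates 1 and 4, and 0.258 without Vav1CreTet2KO replicate 3. A value for the whole gene does not resolve a deleted exon, so these values do not test the genotype labels.

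CD8 T cells with Tet2 removed across blood cells, set against Tet2fl/fl, had lower transcripts of Tox, Tox2 and Ikzf2. These were 3 of 15 tested regulators linked to T cell exhaustion, a list that passed with a preset correlation (camera adjusted p = 0.00775) but not with an estimated one (adjusted p = 0.609). Tox, a transcription factor needed for the exhausted state, fell from 34.4 ± 9.73 to 6.56 ± 3.82 RPKM (n = 3 each), a log2 fold change of -2.34 (SE 0.38, limma adjusted p = 0.0119). Its relative Tox2 fell from 10.3 ± 2.20 to 1.08 ± 0.791 RPKM (log2 fold change -2.49, SE 0.36, limma adjusted p = 0.00993). Ikzf2, the transcription factor Helios, fell from 6.25 ± 0.555 to 1.12 ± 1.06 RPKM (-1.89, SE 0.41, limma adjusted p = 0.0433). The inhibitory receptor Cd200r1 fell 3.81-fold, from 11.3 ± 1.58 to 2.26 ± 0.601 RPKM (limma adjusted p = 0.0112). Prf1, which encodes the pore-forming protein perforin, fell 8.09-fold from 75.6 ± 37.7 to 8.30 ± 3.75 RPKM (limma adjusted p = 0.00799). Cx3cr1, a chemokine receptor of effector cells, fell from 16.8 ± 6.39 to 1.57 ± 0.548 RPKM. Klf3, a transcription factor of resting T cells, rose from 2.72 ± 1.32 to 12.2 ± 4.86 RPKM (1.80, SE 0.37, limma adjusted p = 0.0322). Il7r, the receptor of the survival cytokine interleukin 7, rose from 22.2 ± 5.99 to 65.8 ± 21.6 RPKM (1.51, SE 0.31, limma adjusted p = 0.0339).

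Of 10224 genes tested in this comparison, 46 rose and 102 fell at a limma adjusted p under 0.05, and 1765 had an unadjusted p under 0.05. In all 148 called genes the values of the 3 control and 3 knockout libraries did not overlap. Chance gives this in 10% of genes not chosen by a test. The called genes were chosen on these same values, so the lack of overlap adds no support. Folds are on the log2(RPKM + 1) scale and understate the change of low genes. The median of all tested genes was -0.11, which moved to -0.01 on recovered reads with TMM scaling. With that scaling edgeR called 40 genes higher and 51 lower. With RPKM rescaled by size factors limma called 63 higher and 111 lower. The count was 0 without Tet2fl/fl replicate 1, 42 and 61 without Tet2fl/fl replicates 2 and 3, and 62 without Vav1CreTet2KO replicate 1. It was 88 with pseudocount 0.1, 48 without a filter, 98 with only these groups in the fit and 90 with a replicate block. On recovered reads voom called 93, while DESeq2 called 931, 496 higher and 435 lower, so that the excess of lower genes turned.

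**Figure D2:**
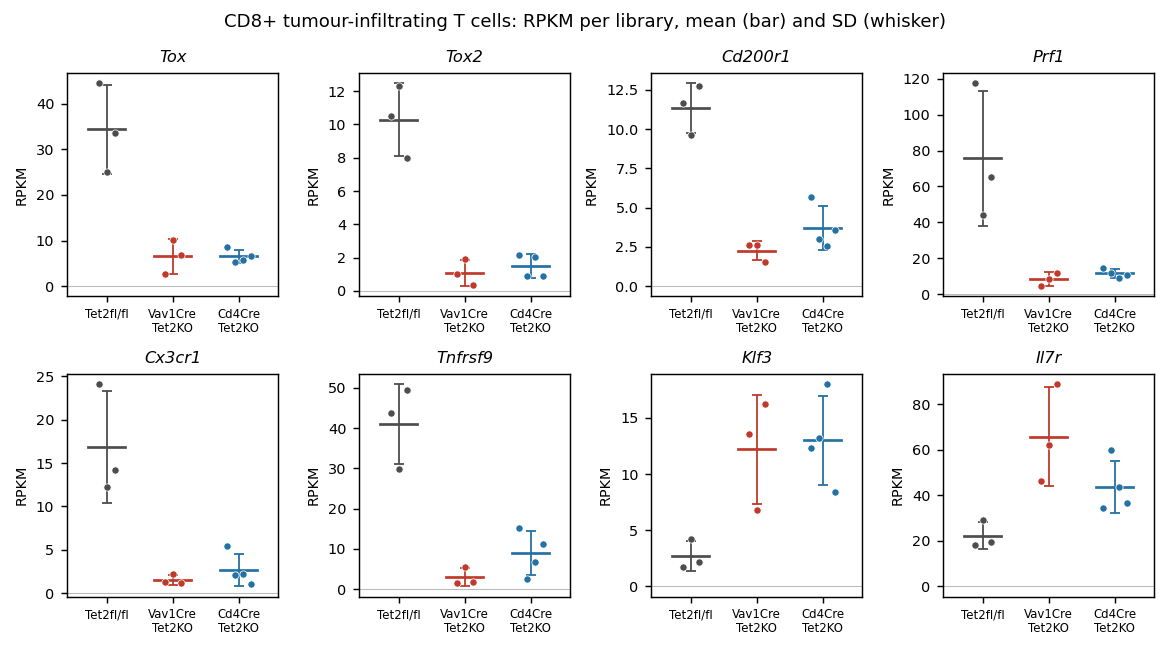
RPKM (y axis) of 8 T cell genes in CD8 libraries of each genotype (x axis), with libraries as points, means as bars and SDs as whiskers. Tox, Tox2, Cd200r1, Prf1 and Cx3cr1 are lower in both knockouts than in Tet2fl/fl and Klf3 is higher, while Tnfrsf9 and Il7r passed the test in Vav1CreTet2KO alone, a difference between the knockouts that did not pass.

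Genes were grouped in lists of known function. Of these, 11 of 31 lists with at least 3 tested members passed limma's camera test with a preset correlation in CD8 Vav1CreTet2KO cells. Of 15 exhaustion-associated regulators, 3 fell (Tox, Tox2 and Ikzf2) and 12 did not pass. When adjusted over the list alone, 7 fell. The list had a median log2 fold change of -0.84 (camera adjusted p = 0.00775, and adjusted p = 0.609 with an estimated correlation). Of 13 inhibitory receptors, 1 fell (Cd200r1), while 5 fell and 1 rose adjusted over the list alone. Their median was -0.88 (camera adjusted p = 0.0161, and adjusted p = 0.609 with an estimated correlation). Lag3, an inhibitory receptor that binds MHC class II, had a log2 fold change of -2.42 (limma adjusted p = 0.0547), and Btla, an inhibitory receptor of resting lymphocytes, one of 1.58 (limma adjusted p = 0.105). Of 14 regulatory T cell genes, 6 fell, and 9 fell adjusted over the list alone. Their median was -1.38 (camera adjusted p = 7.25e-07, and adjusted p = 0.557 with an estimated correlation). They included the costimulatory receptors Tnfrsf9 (41.1 ± 10 to 2.92 ± 2.24 RPKM, limma adjusted p = 0.00993), Tnfrsf4 (log2 fold change -3.88, limma adjusted p = 0.0417) and Tnfrsf18 (-1.75), which activated CD8 T cells also express. The others named were the chemokine receptor Ccr8 (-2.6) and the actin-capping protein Capg (-1.70).

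The naive, stem-like and memory T cell genes had 2 members that rose of 19, Klf3 and Il7r, and 4 adjusted over the list alone (median 0.52, camera adjusted p = 8.48e-04, and adjusted p = 0.609 with an estimated correlation). The members called were 1 with rescaled RPKM and, on recovered reads, 0 with edgeR and 4 with DESeq2. On recovered reads edgeR also called 2 of the exhaustion-associated regulators, 4 of the regulatory T cell genes and 0 of the heat shock genes. Foxp1, a transcription factor of quiescent T cells in that list, had a log2 fold change of 0.75 (limma adjusted p = 0.114). Among 22 cytotoxic effector genes Prf1 and Cx3cr1 fell and Klrk1, an activating receptor shared with natural killer cells, rose (1.64). In that list 3 fell and 1 rose adjusted over the list alone. It did not pass (camera adjusted p = 0.671), and its median of -0.04 turned to 0.06 with rescaled RPKM. Of 13 costimulatory receptors and ligands, 3 fell and 1 rose, and 4 fell and 1 rose adjusted over the list alone. The list did not pass (camera adjusted p = 0.229). The member that rose, Cd40lg, a ligand made mainly by CD4 T cells, went from 0.481 ± 0.752 to 10.4 ± 2.39 RPKM (limma adjusted p = 0.00993). Crtam, an adhesion protein of activated CD8 T cells, fell (-2.07) as 1 of 4 CD8 lineage markers, and 2 fell adjusted over the list alone. Their median was -0.66 (camera adjusted p = 0.0246, and adjusted p = 0.609 with an estimated correlation). Ly6c2, a surface protein of memory and effector CD8 T cells, rose (2.52, limma adjusted p = 0.0160), as did the chemokine receptor Ccr2 (2.38). Lgals4, a galectin of intestinal epithelium, fell (-2.02).

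No member of the glycolysis, interleukin 2 and STAT5 or cell cycle lists passed the test by itself in these cells, although each list did. Of 14 glycolysis genes 4 fell adjusted over the list alone (median -0.71, camera adjusted p = 0.00216, and adjusted p = 0.609 with an estimated correlation). Of 11 interleukin 2 and STAT5 pathway genes 5 fell adjusted over the list alone (median -0.89, camera adjusted p = 0.0095, and adjusted p = 0.609 with an estimated correlation). The 31 cell cycle genes had a median of -0.50 and 0 calls adjusted over the list alone (camera adjusted p = 0.0113, and adjusted p = 0.803 with an estimated correlation). Of 10 heat shock genes, Hspa1a (-3.19) and Hspa1b (-3.26), near-identical copies whose reads may be shared, fell, and 4 fell adjusted over the list alone. Their median was -0.60 (camera adjusted p = 0.0095, and adjusted p = 0.557 with an estimated correlation). Their share of reads was 1.29% against 2.52% in Tet2fl/fl, so it differed between the same groups as Tox, Tox2 and Cd200r1. Whether they varied together within a group was not tested. The number of lists that passed was 5 without Vav1CreTet2KO replicate 3. The fry test of limma, of whether the genes of a list move one way, called 3 (regulatory T cell genes, heat shock genes and CD8 lineage markers, each at adjusted p = 0.048).

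CD8 Vav1CreTet2KO libraries also held more transcripts of some genes of dendritic cells and MHC class II, which presents antigen on dendritic cells, macrophages and B cells. Of 6 tested MHC class II genes 3 rose. H2-Aa went from 24.5 ± 24.9 to 273 ± 135 RPKM (3.77, SE 0.74, limma adjusted p = 0.0285). H2-Ab1 went from 48.6 ± 56.5 to 658 ± 522 RPKM (4.09, SE 0.84, limma adjusted p = 0.0347). Flt3, the growth factor receptor of dendritic cell precursors, rose by 2.72 and Clec9a, a receptor of cross-presenting dendritic cells, by 2.80 (log2, limma adjusted p = 0.0281 and 0.0427). Of 11 dendritic cell and MHC class II genes, 5 rose, and 10 rose adjusted over the list alone (median 2.80, camera adjusted p = 6.04e-11, and adjusted p = 0.557 with an estimated correlation). On recovered reads edgeR called 1 of the 11 and 0 of the MHC class II genes, and DESeq2 called 8. Tyrobp, a signalling adaptor of natural killer and myeloid cells, rose from 3.57 ± 2.93 to 71.1 ± 53.1 RPKM (limma adjusted p = 0.0256). The 12 tested macrophage and monocyte markers had a median of 0.37, or 1.26 on recovered reads with TMM scaling, and did not pass (camera adjusted p = 0.2). Of 26 type I interferon response genes none passed by itself and 8 rose adjusted over the list alone. Their median was 0.94 (camera adjusted p = 2.11e-09, and adjusted p = 0.557 with an estimated correlation). Vav1CreTet2KO replicate 1 stood apart, with a ribosomal share of 11.1%, a mitochondrial share of 3.09% and a median correlation of 0.825 with the other CD8 libraries. H2-Ab1 was at 1256, 428 and 289 RPKM and Tyrobp at 130, 55.0 and 27.9 RPKM in replicates 1 to 3. Without replicate 1 the log2 fold changes of H2-Ab1, H2-Aa and Tyrobp were 3.48, 3.40 and 3.38, and none passed (limma adjusted p = 0.173, 0.148 and 0.139), nor did they without replicate 2 (limma adjusted p = 0.0541, 0.0534 and 0.0505). With dendritic cell genes left out of the table, limma called 127 genes.

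**Figure D3:**
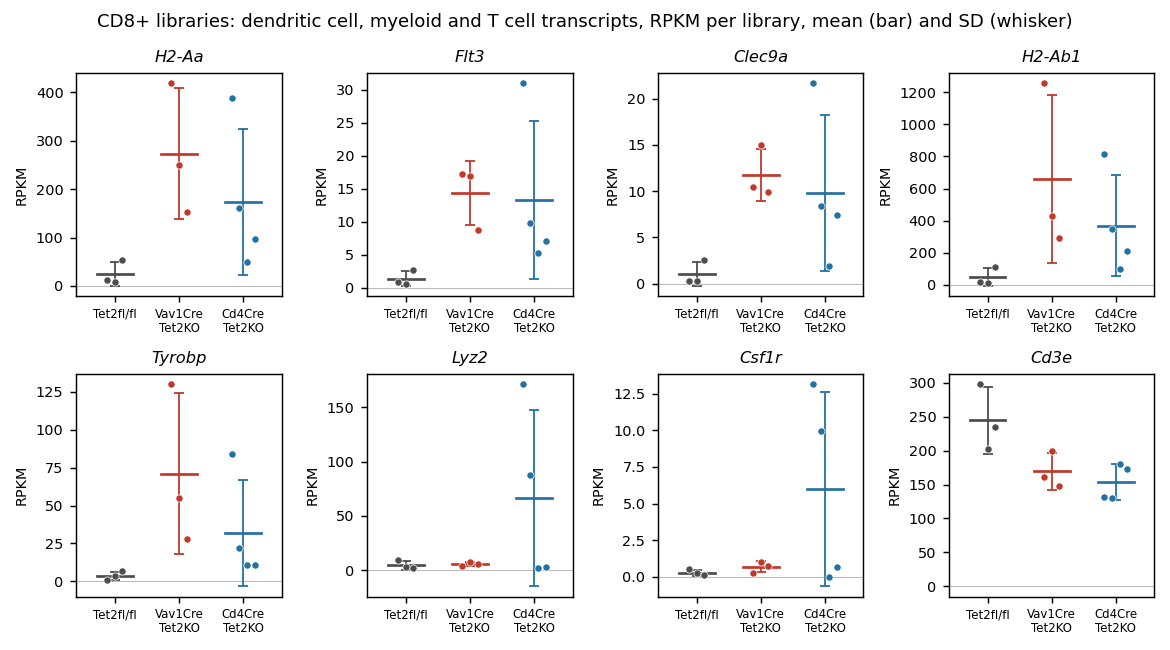
RPKM (y axis) of 7 genes of antigen-presenting and myeloid cells, with the T cell gene Cd3e, in CD8 libraries of each genotype (x axis). Points are libraries, bars are means and whiskers are SDs, and Lyz2 reaches 172 and 88.2 RPKM in Cd4CreTet2KO replicates 1 and 2 while H2-Aa averages 273 RPKM in Vav1CreTet2KO against 24.5 RPKM in Tet2fl/fl.

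CD8 T cells with Tet2 removed in T cells, set against the same controls, had lower Tox, Tox2, Cd200r1 and Prf1. Tox was 6.55 ± 1.42 RPKM (n = 4) against 34.4 ± 9.73 (n = 3), a log2 fold change of -2.21 (SE 0.35, limma adjusted p = 0.0272). Tox2 was 1.5 ± 0.708 RPKM against 10.3 ± 2.20 (-2.20, SE 0.34, limma adjusted p = 0.0272). Cd200r1 fell to 3.70 ± 1.38 RPKM (-1.43, SE 0.28, limma adjusted p = 0.0466) and Prf1 to 11.5 ± 2.32 RPKM (-2.52, SE 0.36, limma adjusted p = 0.0201). Ccl3, a chemokine of activated effector cells, fell from 172 ± 68.7 to 45.4 ± 22.1 RPKM (limma adjusted p = 0.0466). Il18rap, part of the interleukin 18 receptor, fell from 18.6 ± 3.94 to 6.20 ± 0.742 RPKM (limma adjusted p = 0.0325). Klf3 rose from 2.72 ± 1.32 to 13.0 ± 3.95 RPKM (1.92, SE 0.34, limma adjusted p = 0.0325). Pdcd1, the inhibitory receptor PD-1, stood at 22.1 ± 13.4 RPKM against 108 ± 17.8, a log2 fold change of -2.42 that did not pass (limma adjusted p = 0.0625).

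In this comparison 7 genes rose and 45 fell of 10224 (1263 had an unadjusted p under 0.05). In all 52 the groups did not overlap, which chance gives in 2 of 35 arrangements of 3 and 4 libraries for a gene not chosen by a test. These genes were chosen on the same values, so this too adds no support. The median of all tested genes was -0.15, and it was 0.02 on recovered reads with TMM scaling. There edgeR called 36 genes higher and 28 lower, so that the excess of lower genes turned. Rescaled RPKM gave 22 higher and 50 lower, and DESeq2 on recovered reads gave 402 higher and 204 lower. The count was 0, 2 and 0 without Tet2fl/fl replicates 1, 2 and 3, and 10, 0 and 13 without Cd4CreTet2KO replicates 1, 2 and 3. It was 279 with only these groups in the fit, 3 without a filter, 12 with pseudocount 0.1 (7 higher and 5 lower), 0 with a replicate block and 521 with voom on recovered reads. It was also 0 without both libraries that held Lyz2 at 172 and 88.2 RPKM. There the log2 fold change of Tox was -2.27 against -2.21 and that of Prf1 -2.71 against -2.52, with SEs of 0.45 against 0.35 and 0.36 (limma adjusted p = 0.236 and 0.144). For Tox and Prf1 the call thus ended with fewer libraries and larger errors and not with a smaller fold. Whether this held for the other called genes is not given here.

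Inhibitory receptors and exhaustion-associated regulators passed as lists in CD8 Cd4CreTet2KO cells, where 16 of 31 lists passed the camera test and 0 with an estimated correlation. Of 35 splits of the same libraries 4 gave as many lists, the real one included, and the highest other gave 18, so chance was not excluded for the number of lists. Of 13 inhibitory receptors 1 fell, while 8 fell and 1 rose adjusted over the list alone. Their median was -1.39 (camera adjusted p = 1.13e-04, and adjusted p = 0.232 with an estimated correlation). Tigit, an inhibitory receptor of nectin ligands, had a log2 fold change of -1.92 (limma adjusted p = 0.0701). Of 15 exhaustion-associated regulators 2 fell, and 8 fell adjusted over the list alone. Their median was -1.03 (camera adjusted p = 3.09e-07, and adjusted p = 0.156 with an estimated correlation). Prdm1, a transcriptional repressor of effector cells, had a value of -1.85 (limma adjusted p = 0.0514). Of 22 cytotoxic effector genes 3 fell (Prf1, Ccl3 and Cx3cr1, the last to 2.68 ± 1.88 RPKM), and 10 fell adjusted over the list alone. Their median was -0.94 (camera adjusted p = 1.82e-07, and adjusted p = 0.147 with an estimated correlation). Of 14 regulatory T cell genes Ccr8 (-2.13) and Tnfrsf18 (-1.61) fell, and 11 fell adjusted over the list alone. The list's median was -1.38 (camera adjusted p = 2.08e-09, and adjusted p = 0.147 with an estimated correlation). Tnfrsf9 had a log2 fold change of -2.25 (limma adjusted p = 0.0630). The naive, stem-like and memory genes had Klf3 as the 1 member of 19 that rose and 9 adjusted over the list alone. The list's median was 1.04 (camera adjusted p = 1.26e-11, and adjusted p = 0.147 with an estimated correlation). Satb1, a chromatin organiser of resting T cells, had a value of 1.37.

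Of 13 costimulatory receptors and ligands in these cells Tnfrsf18 fell, and 5 fell adjusted over the list alone. The list's median was -0.48 (camera adjusted p = 9.69e-04, and adjusted p = 0.232 with an estimated correlation). Slamf1, a lymphocyte self-ligand, had a value of -1.45. Of 4 CD8 lineage markers Crtam fell (-1.57), and 2 fell adjusted over the list alone (median -0.72, camera adjusted p = 0.00223, and adjusted p = 0.232 with an estimated correlation). No member of the glycolysis or the interleukin 2 and STAT5 list passed by itself, and 3 of the latter fell adjusted over the list alone. The 14 glycolysis genes had a median of -0.53 (camera adjusted p = 0.00245) and the 11 interleukin 2 and STAT5 pathway genes one of -0.54 (camera adjusted p = 0.017). Each had adjusted p = 0.528 with an estimated correlation. Il2rb, a chain of the interleukin 2 receptor, had a log2 fold change of -1.18 and the survival gene Bcl2l1 one of -1.09. The 20 immediate early and T cell receptor-induced genes had a median of -0.53 (camera adjusted p = 0.0273, and adjusted p = 0.62 with an estimated correlation). The activation factor genes Egr2 and Jun stood at -1.36 and -0.81 and the phosphatase gene Dusp1 at -0.81. Of 10 heat shock genes Hsph1 fell (-1.60), and 8 fell adjusted over the list alone, with Dnajb1 at -1.31 and Hspa1b at -2.06. Their median was -0.92 (camera adjusted p = 3.91e-06, and adjusted p = 0.147 with an estimated correlation). The heat shock share was 1.30% against 2.52% in Tet2fl/fl, so it differed between the same groups as the inhibitory receptors, exhaustion-associated regulators and cytotoxic genes. Whether it varied with them within a group was not tested.

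Transcripts of other cell types were higher as lists in the CD8 Cd4CreTet2KO libraries. None of 11 dendritic cell and MHC class II genes passed by itself and 9 rose adjusted over the list alone. Their median was 2.37 (camera adjusted p = 4.21e-13, and adjusted p = 0.147 with an estimated correlation). H2-Ab1 stood at 817, 349, 101 and 212 RPKM in replicates 1 to 4 against 19.8, 12.2 and 114 RPKM in Tet2fl/fl, so that replicate 3 lay below the highest control. None of 12 macrophage and monocyte markers passed by itself, and their median was 0.84 (camera adjusted p = 1.35e-05, and adjusted p = 0.346 with an estimated correlation). It was 3.06 on recovered reads with TMM scaling, where folds of low genes are not damped and the dendritic cell and MHC class II list stood at 3.02. They moved with the Lyz2 and Csf1r levels of replicates 1 and 2. B and plasma cell markers had 7 tested members, of which 2 rose adjusted over the list alone. Their median was 1.19 (camera adjusted p = 3.55e-06, and adjusted p = 0.147 with an estimated correlation). The 3 endothelial markers had a median of 0.73 (camera adjusted p = 0.0112, and adjusted p = 0.147 with an estimated correlation). The 26 type I interferon response genes had a median of 0.67 and 0 calls adjusted over the list alone (camera adjusted p = 3.44e-09, and adjusted p = 0.232 with an estimated correlation). Within it the antiviral genes Mx1 and Oas3 had values of 1.13 and 1 and the exonuclease Isg20 one of -1.27. The fry test called 8 lists, all with lower genes.

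**Figure D4:**
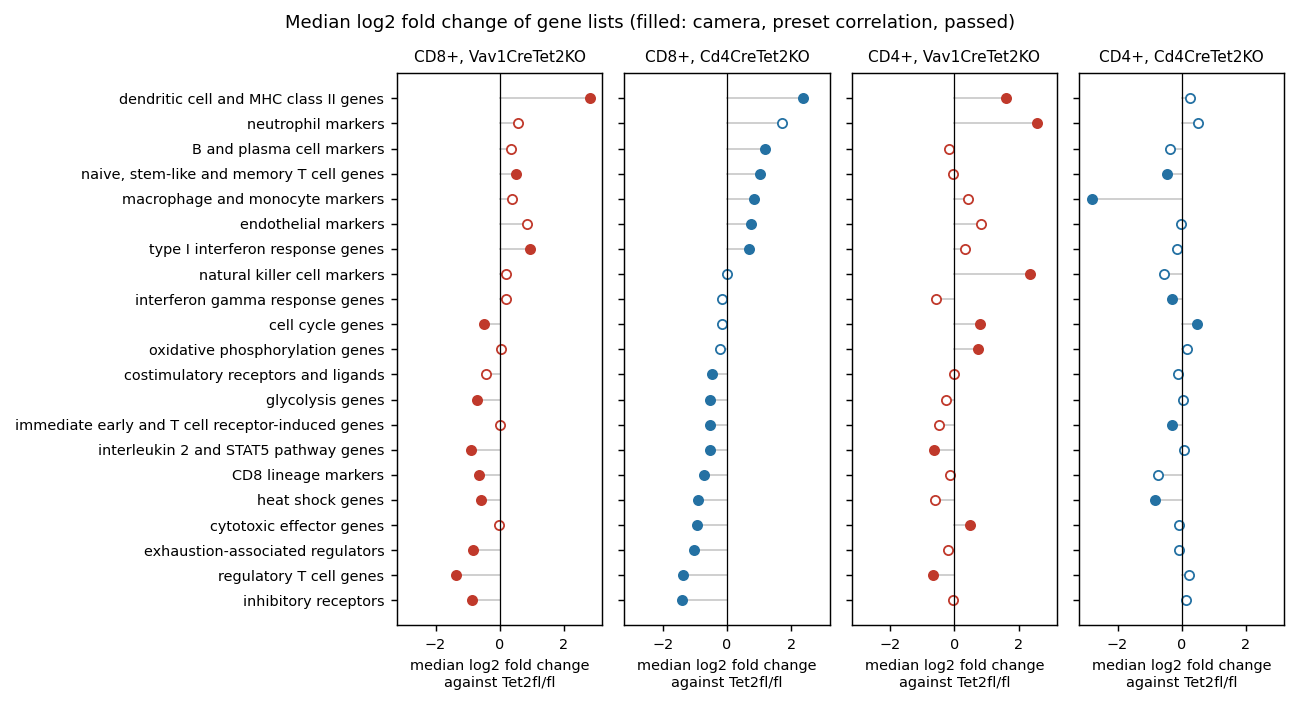
Median log2 fold change against Tet2fl/fl (x axis) of the members of each gene list (y axis), for both knockouts in CD8 and CD4 cells. Points are medians over genes, and in CD8 cells the dendritic cell and MHC class II list lies at 2.80 and 2.37 and the inhibitory receptors at -0.88 and -1.39.

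CD8 cells of the knockouts were compared with each other to ask whether Tet2 loss across blood cells differed from loss in T cells. No gene passed (limma, smallest adjusted p = 0.139), and 647 genes had an unadjusted p under 0.05. DESeq2 on recovered reads called 95, and edgeR and voom on recovered reads called 0. Ccl5, a chemokine of effector and memory T cells, stood at 1712 ± 1160 RPKM in Vav1CreTet2KO (n = 3) and 462 ± 25.0 in Cd4CreTet2KO (n = 4), a log2 fold change of 1.67 (SE 0.37, limma adjusted p = 0.697). Ccl5 was at 3020, 1309 and 807 RPKM in Vav1CreTet2KO replicates 1 to 3, and without replicate 1 the log2 fold change was 1.16 (SE 0.23, limma adjusted p = 0.439). The other named members had limma adjusted p = 0.723. Among cytotoxic and inhibitory genes these were the cytokine gene Tnf (1.18), the effector transcription factor Tbx21 (1.08), and the receptors Ctla4 (1.59), Cd38 (0.60) and Cd160 (0.48). Among regulators and memory genes they were the receptor-induced factors Nr4a1 (1.05), Nr4a2 (1.83) and Nr4a3 (1.99) and Bach2 (-0.99), Cxcr5 (-1.06) and S1pr1 (-1.5).

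Between the knockouts, 8 of 31 lists passed the camera test in CD8 cells. Of 22 cytotoxic effector genes 9 were higher in Vav1CreTet2KO adjusted over the list alone (median 0.75, camera adjusted p = 1.26e-05, and adjusted p = 0.604 with an estimated correlation). So were 2 of 11 T helper 1 genes (median 0.39, camera adjusted p = 0.0134, and adjusted p = 0.515 with an estimated correlation). Immediate early genes (median 0.39, camera adjusted p = 0.0244) and type I interferon response genes (median 0.24, camera adjusted p = 0.0463) were higher as lists, each at adjusted p = 0.782 with an estimated correlation. Cell cycle genes (median -0.26, camera adjusted p = 0.00401), macrophage and monocyte markers (-0.86, camera adjusted p = 0.0244) and naive, stem-like and memory genes (-0.38, camera adjusted p = 0.03) were lower, each at adjusted p = 0.782 with an estimated correlation. B and plasma cell markers were lower (-0.84, camera adjusted p = 0.00439, and adjusted p = 0.604 with an estimated correlation), and fry called 0 lists. The number of lists was 4 without Cd4CreTet2KO replicate 2, 5 without Vav1CreTet2KO replicate 2 and 4 without Vav1CreTet2KO replicate 3. The gene test of limma called 1 gene without Cd4CreTet2KO replicate 3 or Vav1CreTet2KO replicate 2.

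Both CD8 comparisons shared the Tet2fl/fl libraries, and 46 genes were called in both, 6 higher and 40 lower, with 0 in opposite directions. Tox, Tox2, Cd200r1, Prf1, Cx3cr1, Ccr8, Tnfrsf18, Crtam and Klf3 were among them. Independent lists of these sizes would share 0.0315 higher and 0.449 lower genes, and 100 simulations of unchanged groups against the same controls shared a median of 0 and at most 1. Unchanged groups leave few called genes to share. The simulated overlap therefore does not show what shared controls would give for lists of the real sizes. Log2 fold changes correlated across genes at r = 0.73 against a simulated mean of 0.54, and their covariance of 0.264 exceeded the simulated 0.077 by 0.187. Genes are not independent replicates. With 3 controls these could not be split, and part of the excess may come from the shared controls. The overlap was 0 without Tet2fl/fl replicate 1 or 3, 2 without Tet2fl/fl replicate 2, 9, 0, 11 and 29 without Cd4CreTet2KO replicates 1 to 4, and 79 without Vav1CreTet2KO replicate 2. In CD4 cells 0 genes were called in both comparisons by edgeR and 24 by DESeq2. The log2 fold changes of all tested genes there had r = 0.33 against a simulated 0.50 and a covariance of 0.528 against 0.747.

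In CD4 T cells of Vav1CreTet2KO mice, 1 gene passed against Tet2fl/fl. Ccnb1ip1, a ubiquitin ligase known for its part in meiotic crossing over, rose 6.88-fold from 162 ± 43.3 to 1115 ± 340 CPM (counts scaled to library size, n = 3 each, log2 fold change 2.78, SE 0.31, edgeR adjusted p = 0.00486). It was chosen after its values were seen, and it also rose in CD8 cells of the same genotype (3.29, limma adjusted p = 0.0113). Both cell types came from the same knockout and control animals, so this rise is not independent of the first. Values that did not pass included the inhibitory receptors Pdcd1, at 64.3 ± 11.9 CPM against 162 ± 27.3 (-1.33, edgeR adjusted p = 0.153), and Tigit (-1.30). Lag3 had a log2 fold change of 1.83, Ikzf2 one of -1.02 and Tox2 one of -1.83. The cytokine signalling inhibitor Socs3 stood at 160 ± 9.15 CPM against 515 ± 82.2 (-1.68, edgeR adjusted p = 0.0744), the kinase Jak3 at -1.36 and the STAT5 target Cish at -0.76.

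Of 13554 genes tested, 1617 had an unadjusted p under 0.05, DESeq2 called 581, edgeR without a filter 383 and voom with quality weights 1. The median of all genes was -0.16 under TMM, RLE and DESeq2 scaling. The count was 0 without Tet2fl/fl replicate 1 or 2, 19, 3 and 819 without Vav1CreTet2KO replicates 1, 2 and 3, and 3 with a block for replicate number.

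In these CD4 cells 8 of 35 lists passed the camera test, none of them with a member that passed by itself. The 31 cell cycle genes had a median of 0.79, and 2 rose adjusted over the list alone (camera adjusted p = 4.72e-07, and adjusted p = 0.314 with an estimated correlation). The motor protein genes Cenpe and Kif11 stood at 2.63 and 1.39 and the chromatin protein gene Hmgb2 at 1.57. The 22 oxidative phosphorylation genes had a median of 0.75, and 3 rose adjusted over the list alone (camera adjusted p = 1.45e-04, and adjusted p = 0.314 with an estimated correlation). The respiratory chain genes Cox6c, Cox4i1 and Ndufa2 stood at 2.42, 1.68 and 2.25. Vav1CreTet2KO replicates 1 and 2 stood apart in these genes. Cox6c was at 322, 327 and 34.9 RPKM in replicates 1 to 3 against 65.9, 35.5 and 34.1 RPKM in Tet2fl/fl, and Cenpe at 18.0, 11.6 and 2.64 RPKM against 1.74, 2.57 and 1.24 RPKM. The ribosomal share was 8.94% in each of replicates 1 and 2 and 6.37% in replicate 3. Of 22 cytotoxic effector genes 7 rose adjusted over the list alone (median 0.48, camera adjusted p = 6.2e-04, and adjusted p = 0.314 with an estimated correlation), with Klrk1 at 4.95 and Ccl5 at 1.47. Of 12 interleukin 2 and STAT5 pathway genes 2 fell adjusted over the list alone (median -0.64, camera adjusted p = 0.0344, and adjusted p = 0.56 with an estimated correlation). So did 2 of 18 regulatory T cell genes (median -0.66, camera adjusted p = 0.0373, and adjusted p = 0.647 with an estimated correlation). Il1rl1, the interleukin 33 receptor of tissue regulatory T cells, had a value of -1.59. Inhibitory receptors (camera adjusted p = 0.755), exhaustion-associated regulators (camera adjusted p = 0.607) and heat shock genes (median -0.62, camera adjusted p = 0.108) did not pass. The naive and memory genes Bcl2, Dapl1 and Xcl1 had values of -1, 2.53 and 2.6.

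Genes of other cell types were higher as lists in the CD4 Vav1CreTet2KO libraries. Of 11 dendritic cell and MHC class II genes 4 rose adjusted over the list alone (median 1.61, camera adjusted p = 1.45e-04, and adjusted p = 0.314 with an estimated correlation). H2-Ab1 stood at 582 ± 278 CPM against 85.7 ± 36.3 (2.76, edgeR adjusted p = 0.110), H2-Eb1 at a log2 fold change of 2.66 and the class II chaperone gene Cd74 at 950 ± 139 CPM against 260 ± 111. Of 6 natural killer cell markers 2 rose adjusted over the list alone (median 2.37, camera adjusted p = 1.45e-04, and adjusted p = 0.314 with an estimated correlation). The signalling adaptor gene Tyrobp stood at 165 ± 76.4 CPM against 14.3 ± 11.5, and Fcer1g had a log2 fold change of 2.42. The 4 neutrophil markers had a median of 2.57 (camera adjusted p = 0.0344, and adjusted p = 0.314 with an estimated correlation). Ribosomal protein transcripts took 8.08% of reads in these libraries against 4.97% in Tet2fl/fl. Fry called 0 lists, and the number that passed camera was 5 without Tet2fl/fl replicate 2, 13 without Vav1CreTet2KO replicate 1 and 5 without Vav1CreTet2KO replicate 3.

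In CD4 T cells of Cd4CreTet2KO mice, 1 gene rose and 3 fell against Tet2fl/fl, all 4 chosen for naming after their values were seen. Gh, growth hormone, a product of the pituitary (ENSMUSG00000020713, chromosome 11, 106191097 to 106192691 as the table gives it), was the gene that rose. It reached 94.4 ± 21.5 CPM (n = 3, edgeR adjusted p = 0.00818). It had 0 reads in all 6 CD4 libraries of the other genotypes. The lowest Cd4CreTet2KO library, at 70.1 CPM, was at least 1490-fold higher than the floor of 3 counts over these 6 libraries (0.0471 CPM). Rps18-ps6 fell from 104 ± 36.3 to 5.53 ± 3.55 CPM (-4.22, edgeR adjusted p = 0.00818) and Gm5148 from 184.05 ± 15.1 to 6.84 ± 4.33 CPM (-4.75, edgeR adjusted p = 0.0126). Gm45234 fell from 138 ± 70.6 CPM to 0 counts in all 3 libraries (edgeR adjusted p = 0.0220). Rps18-ps6 is a pseudogene and the Gm genes are models without a given name, whose reads may be shared with other genes, so their values are uncertain.

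**Figure D5:**
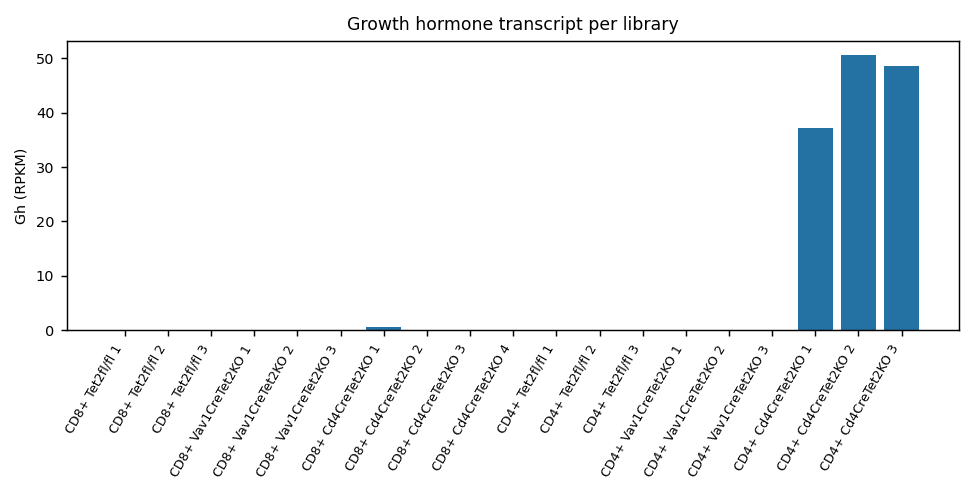
Gh expression (y axis, RPKM) in each library of the genotypes of CD8 and CD4 cells (x axis), where each bar is a single library. The 3 CD4 Cd4CreTet2KO libraries sit at 37.2, 50.7 and 48.5 RPKM, and CD8 Cd4CreTet2KO replicates 1 and 2 hold 24 and 3 reads.

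Of 13554 genes tested in that comparison 339 had an unadjusted p under 0.05, DESeq2 called 47 (27 higher and 20 lower) and edgeR without a filter 37. The count was 2 without Cd4CreTet2KO replicate 1, 0 without Cd4CreTet2KO replicate 2, and 8 with only these 6 libraries in the fit. Pdcd1 (0.39), Havcr2 (1.12) and Ctla4 (0.64), inhibitory receptors, did not pass (edgeR adjusted p = 0.9998). Nor did the exhaustion-associated Nr4a2 (1.08), Nr4a3 (0.76) and Rbpj (0.67), the naive and memory genes Tcf7 (-0.77), Klf2 (-0.98) and Bcl2 (-0.93), or the cytokine gene Ifng (-1.08). As lists, exhaustion-associated regulators (median -0.09), inhibitory receptors (0.12) and dendritic cell and MHC class II genes (0.26) did not pass (camera adjusted p = 0.745 each).

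In these CD4 cells 6 of 35 lists passed the camera test and fry called 0. Of 10 heat shock genes 4 fell adjusted over the list alone (median -0.84, camera adjusted p = 7.08e-09, and adjusted p = 0.19 with an estimated correlation), and their share of reads was 1.23% against 2.90% in Tet2fl/fl. The constitutive chaperone gene Hspa8 stood at 2831 ± 323 CPM against 5037 ± 243 (-0.83, edgeR adjusted p = 0.991), and Dnajb1 and Hsph1 had log2 fold changes of -2.22 and -1.31. The 11 macrophage and monocyte markers had a median of -2.78 (camera adjusted p = 1.16e-05, and adjusted p = 0.617 with an estimated correlation). Lyz2, the lipid carrier gene Apoe and Csf1r stood at -3.36, -2.29 and -2.59. These values moved with Tet2fl/fl replicates 1 and 3. Lyz2 was at 20.1, 0.36 and 40.1 RPKM in the controls against 3.89, 0.41 and 1.55 RPKM, and Apoe at 25.3, 3.70 and 32.1 RPKM against 4.71, 3.08 and 4.06 RPKM. Cell cycle genes were higher as a list (31 tested, median 0.47, camera adjusted p = 1.6e-05, and adjusted p = 0.617 with an estimated correlation). The mitotic genes Cenpe, Bub1b and Cdc20 stood at 1.34, 1.33 and 1.83. Interferon gamma response genes were lower (19 tested, median -0.29, camera adjusted p = 4.39e-04, and adjusted p = 0.617 with an estimated correlation). The resistance GTPase genes Igtp, Iigp1 and Tgtp2 stood at -0.80, -0.91 and -0.89. Naive, stem-like and memory genes (median -0.45, camera adjusted p = 0.00468) and immediate early genes (median -0.30, camera adjusted p = 0.0349) were lower, each at adjusted p = 0.662 with an estimated correlation. Jun, Egr1 and the phosphatase gene Dusp5 stood at -1.01, -0.58 and 0.79. The number of lists was 2 without Tet2fl/fl replicate 3.

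CD4 cells of the knockouts were compared with each other. In them 6 genes were higher and 3 lower in Vav1CreTet2KO than in Cd4CreTet2KO, of which 8 were chosen for naming after their values were seen. The ribosomal protein gene Rps29 (log2 fold change 2.15, edgeR adjusted p = 0.0390) and Ccnb1ip1 (1.83, edgeR adjusted p = 0.0418) were higher, as were Gm5148 (7.32), Rps18-ps6 (5.36) and Gm45234, whose reads may be shared. Lamc1, a laminin chain, was lower at 93.2 ± 38.3 CPM against 477 ± 161 (n = 3 each, -2.34, edgeR adjusted p = 0.0265). Itgav, an integrin chain, was lower at 117 ± 29.3 CPM against 510 ± 221 (-2.11, edgeR adjusted p = 0.0418), and Gh was at 0 in Vav1CreTet2KO (edgeR adjusted p = 0.00894). Pdcd1 (-1.71, edgeR adjusted p = 0.0751), Ikzf2 (-1.35), Tigit (-1.18) and Rbpj (-0.82) did not pass, nor did Ifng (1.94), Ccl5 (1.39) and Srgn (1.37). Of 13554 genes 1449 had an unadjusted p under 0.05. DESeq2 called 516, voom 73, and edgeR 403 without a filter and 3 with only these groups in the fit. The count was 5, 2 and 5 without Cd4CreTet2KO replicates 1, 2 and 3, and 22 and 719 without Vav1CreTet2KO replicates 1 and 3.

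Between the knockouts 12 of 35 lists passed the camera test in CD4 cells. Higher as lists in Vav1CreTet2KO were 22 cytotoxic effector genes (4 rose adjusted over the list alone, median 1.17, camera adjusted p = 1.95e-05) and 6 natural killer cell markers (2 rose adjusted over the list alone, median 3.29, camera adjusted p = 3.95e-05). So were 22 oxidative phosphorylation genes (3 rose adjusted over the list alone, median 0.97, camera adjusted p = 5.84e-05), 11 dendritic cell and MHC class II genes (4 rose adjusted over the list alone, median 1.30, camera adjusted p = 1.36e-04) and 4 neutrophil markers (median 1.93, camera adjusted p = 0.0231). Each of these had adjusted p = 0.311 with an estimated correlation. Cox6c, at 322, 327 and 34.9 RPKM in Vav1CreTet2KO against 81.7, 39.5 and 42.3 RPKM, was higher in replicates 1 and 2 alone. Macrophage and monocyte markers were higher too (11 tested, 3 rose adjusted over the list alone, median 3.01, camera adjusted p = 1.95e-05, and adjusted p = 0.432 with an estimated correlation). So were type I interferon response genes (median 0.47, camera adjusted p = 0.00854, and adjusted p = 0.55 with an estimated correlation). Naive, stem-like and memory genes (median 0.27, camera adjusted p = 0.0177) and cell cycle genes (median 0.26, camera adjusted p = 0.0231) were higher, each at adjusted p = 0.655 with an estimated correlation. Regulatory T cell genes were lower (18 tested, 4 fell adjusted over the list alone, median -0.86, camera adjusted p = 0.0138, and adjusted p = 0.655 with an estimated correlation). So were interleukin 2 and STAT5 pathway genes (12 tested, 6 fell adjusted over the list alone, median -0.88, camera adjusted p = 0.0207, and adjusted p = 0.459 with an estimated correlation). T helper 2 genes were lower as well (8 tested, 1 fell adjusted over the list alone, median -1.54, camera adjusted p = 0.0247, and adjusted p = 0.311 with an estimated correlation). Fry called the interleukin 2 and T helper 2 lists, each at adjusted p = 0.024, and 7 lists passed camera without Vav1CreTet2KO replicate 3. In every list that passed in the 6 comparisons the median, the mean and the test had the same sign.

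Whether a knockout's effect differed between CD8 and CD4 cells was tested as an interaction on log2(RPKM + 1), with tables that had been normalized separately. For Vav1CreTet2KO 0 genes passed (limma, 11121 tested, smallest adjusted p = 0.0581, 1022 at an unadjusted p under 0.05). By other tools, edgeR on counts and recovered reads called 4 and DESeq2 called 180, and limma called 8 on rescaled RPKM. The limma count was 6 and 10 without CD8 Tet2fl/fl replicate 2 and CD8 Vav1CreTet2KO replicate 2, and 1 and 153 without CD4 Vav1CreTet2KO replicates 1 and 3. A block for animal called 1. So the falls of Tox, Tox2 and Prf1 in CD8 Vav1CreTet2KO cells were not shown to differ from their values in CD4 cells. Lists that differed were cell cycle (-1.04, camera adjusted p = 8.12e-11), cytotoxic (-0.65, 4.9e-05) and interferon gamma response genes (0.87, 6.98e-04), each at adjusted p = 0.436 with an estimated correlation. Inhibitory receptors (-0.49, camera adjusted p = 0.00401) had adjusted p = 0.552 with an estimated correlation. Dendritic cell and MHC class II (1.47, camera adjusted p = 0.00401), type I interferon (0.76, 0.00501), oxidative phosphorylation (-0.52, 0.00552) and naive, stem-like and memory genes (0.97, 0.0101) had adjusted p = 0.675 with an estimated correlation. Immediate early genes (0.65, camera adjusted p = 0.0203) had adjusted p = 0.676 with an estimated correlation.

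For Cd4CreTet2KO 7 of 11121 genes differed between the cell types, 2 with a higher and 5 with a lower effect in CD8 cells (630 at an unadjusted p under 0.05). Gh had a log2 fold change of 0.20 in CD8 and 5.53 in CD4 cells (difference -5.33, SE 0.36, limma adjusted p = 6.74e-08). Nrn1, a membrane-anchored protein first studied in neurons, had values of -2.05 and 2.44 (difference -4.49, SE 0.75, limma adjusted p = 0.0275). The others with a lower effect were Ccdc184 (difference -2.84, limma adjusted p = 0.00849), Ablim3, an actin-binding protein (-3.34, limma adjusted p = 0.0427), and the collagen receptor gene Mrc2 (-2.67, limma adjusted p = 0.0427). Gm42733 (2.33, limma adjusted p = 0.0427) and Rps18-ps6 (4.21, limma adjusted p = 0.0275), whose reads may be shared, had a higher one. The count was 2 without a filter, 2 with edgeR and 141 with DESeq2 on counts and recovered reads, and 2 without both CD8 libraries that held Lyz2 at 172 and 88.2 RPKM. With a block for animal 0 genes passed, as with the 8 animals of both cell types and no block, where Gh was too low in too many libraries to be tested. Nrn1 had a blocked difference of -4.33 (limma adjusted p = 0.138). Without single libraries the count was 4, 3 and 3 (CD8 Cd4CreTet2KO replicates 1 to 3), 2, 3 and 2 (CD8 Tet2fl/fl replicates 1 to 3), 1, 1 and 0 (CD4 Cd4CreTet2KO replicates 1 to 3) and 3, 1 and 2 (CD4 Tet2fl/fl replicates 1 to 3).

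The lists gave more differences between the cell types for Cd4CreTet2KO, with 16 past the camera test, which does not take account of shared animals. Fry called 0 lists for either knockout (smallest adjusted p = 0.145 for Cd4CreTet2KO and 0.284 for Vav1CreTet2KO). Naive, stem-like and memory genes (1.66, camera adjusted p = 4.28e-14, and adjusted p = 0.151 with an estimated correlation) and macrophage markers (1.81, camera adjusted p = 2.96e-08, and adjusted p = 0.216 with an estimated correlation) had higher effects in CD8 cells. So did type I interferon response genes (0.77, camera adjusted p = 1.36e-07, and adjusted p = 0.197 with an estimated correlation) and B and plasma cell markers (1.26, camera adjusted p = 1.47e-05, and adjusted p = 0.159 with an estimated correlation). Dendritic cell and MHC class II genes (2.31, camera adjusted p = 1.45e-10) were higher, and regulatory T cell genes (-1.43, 5.5e-08), exhaustion-associated regulators (-1.41, 1.08e-06) and inhibitory receptors (-1.23, 1.05e-05) lower, each at adjusted p = 0.164 with an estimated correlation. Cytotoxic effector genes (-0.74, camera adjusted p = 1.99e-04, and adjusted p = 0.196 with an estimated correlation) and cell cycle genes (-0.54, camera adjusted p = 3.63e-04, and adjusted p = 0.431 with an estimated correlation) had lower effects. So did glycolysis genes (-0.59, camera adjusted p = 0.00559, and adjusted p = 0.421 with an estimated correlation) and costimulatory receptors (-0.71, camera adjusted p = 0.0143, and adjusted p = 0.261 with an estimated correlation). Interleukin 2 and STAT5 genes were lower (-0.56, camera adjusted p = 0.0428, and adjusted p = 0.456 with an estimated correlation), and neutrophil markers (1.47, camera adjusted p = 0.0277, and adjusted p = 0.338 with an estimated correlation) higher. Endothelial markers (0.99, camera adjusted p = 0.0228) and interferon gamma response genes (0.11, camera adjusted p = 0.0126) each had adjusted p = 0.346 with an estimated correlation. Macrophage markers moved here with the Lyz2 levels of CD8 Cd4CreTet2KO replicates 1 and 2 and of CD4 Tet2fl/fl replicates 1 and 3, where Lyz2 was at 20.1 and 40.1 RPKM against 0.36 RPKM in replicate 2.

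The authors' deposited table of CD8 fold changes listed 320 genes higher and 190 lower in Vav1CreTet2KO at a false discovery rate under 0.05, of which 45 and 87 were called here too. For CD8 Cd4CreTet2KO the authors' deposited table listed 317 higher and 151 lower, of which 7 and 41 were shared. For CD4 Vav1CreTet2KO the authors' deposited table listed 158 higher and 65 lower, of which 1 and 0 were shared. For CD4 Cd4CreTet2KO the authors' deposited table listed 4 higher and 11 lower, of which 1 and 3 were shared.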

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

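The tests of an explanation for a pattern and the splits of animals in this part were chosen after the results were seen. The test of whether an effect differs between cell types, its splits within each cell type and the search for a library far from its group were planned.

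Among groups of 4 libraries, Tyrobp, a signalling adaptor of natural killer and myeloid cells, stood far above the rest of its group in CD8 Cd4CreTet2KO replicate 1, at 84.1 RPKM. It was the only one of 60 genes tested in this way. Chance marks about 1 in 20 groups, so 1 of 60 is no more than chance gives. Lyz2 and Csf1r, genes of macrophages, were also highest in that library among the CD8 libraries, at 172 and 13.2 RPKM. The difference between CD8 and CD4 cells in the effect of Cd4CreTet2KO passed the interaction test for 7 genes: the log2 difference was -5.33 for Gh, -4.49 for Nrn1, -3.34 for Ablim3, -2.84 for Ccdc184, -2.67 for Mrc2, 2.33 for Gm42733 and 4.21 for Rps18-ps6. Of 100 splits drawn within each cell type, 2 gave 7 or more genes, the real one included (highest other 16). These can part libraries of the same animal. Of the 30 splits that keep them together, 1 gave 7 or more, the real one (highest other 2). At 1 of 30, chance was excluded for the count without an animal block. With the block, Gh was untested and none of the other 6 passed.

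Dendritic cell and MHC class II genes were higher as a list in both CD8 knockouts, with 5 and 0 of 11 genes past the test in Vav1CreTet2KO and Cd4CreTet2KO and adjusted p = 0.557 and 0.147 with an estimated correlation. Genes outside MHC class II argue against MHC class II made by the CD8 T cells as the whole cause. Of dendritic cell genes, 31 outside MHC class II had a median log2 fold change of at least 1.48 in both knockouts. These were gathered after the results were seen and included 9 already called in Vav1CreTet2KO, which raises their median. The argument therefore rests on the 19 of them called in neither knockout, given next. Dendritic cells among the sorted cells may be a source: 19 added markers of plasmacytoid and conventional dendritic cells, outside the planned list and called in neither knockout, but from lists that also held genes already seen to rise, had medians of 1.78 and 1.30. The sort on CD3ε would remove such cells, and whether dendritic cells differ in number between the genotypes was not tested. Macrophages stay open as a further source, since their markers had medians of 0.37 and 0.84 in Vav1CreTet2KO and Cd4CreTet2KO. On recovered reads, where 15 of these markers were tested instead of 12, the medians were 1.18 and 3.34, against 3.07 and 2.77 for the added dendritic cell markers there.

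Gh reads stood at 37.2 RPKM or more in the 3 CD4 libraries of Cd4CreTet2KO animals, at 24 and 3 reads in CD8 replicates 1 and 2 of that genotype and at 0 elsewhere. RNA from pituitary tissue was excluded as the source, since Prl, the other abundant hormone transcript of such cells, was at 0 RPKM in every one of these CD4 libraries. A candidate explanation is a growth hormone sequence carried with the Cd4-Cre transgene, as some Cre constructs carry one. The values that prompted it, at least 37.2 RPKM in Cd4-Cre CD4 libraries and 0 in animals without that Cre, cannot test it. It was predicted that Gh would reach 1 RPKM in the CD8 libraries of Cd4-Cre animals too. This was not met, at 0.626, 0.0589, 0 and 0 RPKM in replicates 1 to 4. Replicates 3 and 4 came from animals whose CD4 libraries held Gh at 37.2 and 48.5 RPKM. The transcript of Cd4 itself stood at 7.68, 2.27, 0 and 0.0158 RPKM in these CD8 libraries. It stood at 84.8 to 114 RPKM in the CD4 libraries of that genotype. A transgene transcribed only where Cd4 is would stay low in CD8 cells, so the unmet prediction does not decide the question. The sequence of the reads was not examined, so the hypothesis stays open.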

How the results depend on the processing

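The count tests on recovered reads, rescaled RPKM, the CD8 comparison without libraries holding macrophage markers and the one without dendritic cell genes were chosen after seeing the data. Of 326 values of counts, lists and Tet2 under another setting, 205 stayed on the same side or within 1.5 times, 113 moved and 8 changed sign. Unless the construction shows it (fewer genes, fewer samples), the cause was not tested. Named genes other than Tet2 never changed sign. In CD8 Vav1CreTet2KO 334 of 518 values of 29 genes held, 179 lost and 5 gained the threshold. In CD8 Cd4CreTet2KO 391 of 551 held, 121 lost and 39 gained it, and for the interaction of Cd4CreTet2KO 99 of 142 lost it. Between the knockouts 227 of 228 held in CD8 and 149 of 169 in CD4 cells, and in CD4 cells 54 of 377 values gained it for Vav1CreTet2KO and 11 of 351 for Cd4CreTet2KO. Calls in CD8 cells rest on few libraries. They fell to 0 for Vav1CreTet2KO without Tet2fl/fl replicate 1 and for Cd4CreTet2KO without Cd4CreTet2KO replicate 2, among others. CD4 Vav1CreTet2KO replicate 1 was the shallowest library, with 707866 reads, but the highest left-out count of that comparison, 819, came without replicate 3.

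For CD8 Vav1CreTet2KO (148 genes) limma called 88 with pseudocount 0.1, 48 without a filter, which adds genes to the adjustment, and 98 with only these groups, and on recovered reads edgeR with TMM called 91, voom 93 and DESeq2 931. For CD8 Cd4CreTet2KO (52) the same settings gave 12, 3 and 279, voom 521 and DESeq2 606, and without the libraries holding macrophage markers 0. Between the knockouts in CD8 cells (0) only these groups gave 2 and DESeq2 95. The CD8 overlap (46) was 3 without a filter, 418 with DESeq2 and 0 without the libraries holding macrophage markers. Without a filter edgeR called 383, 37 and 403 in the CD4 comparisons (Vav1CreTet2KO, Cd4CreTet2KO and between them, 1, 4 and 9 otherwise) and DESeq2 581, 47 and 516. Only the compared groups gave 8 for CD4 Cd4CreTet2KO and 3 between the knockouts, where voom gave 73. The CD4 overlap (0) was 14 without a filter and 24 with DESeq2. The interaction of Vav1CreTet2KO (0) was 4 with edgeR TMM, 6 with RLE, 180 with DESeq2 and 8 with rescaled RPKM, and that of Cd4CreTet2KO (7) was 2, 3 and 141, and 2 without a filter, 2 without the libraries holding macrophage markers and 0 with only the animals of both cell types. List calls were 0 in all 6 comparisons with an estimated correlation, and with fry 3, 8 and 0 in CD8 cells and 0, 0 and 2 in CD4 cells (Vav1CreTet2KO, Cd4CreTet2KO and between them).

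Libraries with the same replicate number in different genotypes were not paired: their deviations correlated at -0.08 to 0.07 in CD8 and -0.05 to 0.06 in CD4 cells. A replicate block gave 90 genes for CD8 Vav1CreTet2KO, 0 for CD8 Cd4CreTet2KO and for the CD8 overlap, 3 for CD4 Vav1CreTet2KO and 0.006 for Tet2 between the CD8 knockouts. A block for animal gave 1 gene for the interaction of Vav1CreTet2KO and 0 for that of Cd4CreTet2KO, and the block moved no other count by over 1.5 times. Tet2 between the CD8 knockouts (-0.01) was 0.221 without the libraries holding macrophage markers.

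With each library left out in turn, genes called ranged over 0 to 211 for CD8 Vav1CreTet2KO, 0 to 40 for CD8 Cd4CreTet2KO, 0 to 1 between them, 0 to 819 for CD4 Vav1CreTet2KO, 0 to 4 for CD4 Cd4CreTet2KO and 2 to 719 between them. The CD8 overlap ranged over 0 to 79 and the CD4 overlap stayed at 0, and the interactions over 0 to 153 for Vav1CreTet2KO and 0 to 5 for Cd4CreTet2KO. List calls ranged over 5 to 12, 13 to 17 and 4 to 10 in CD8 cells and 5 to 13, 2 to 6 and 7 to 15 in CD4 cells. Tet2 ranged over -0.725 to -0.280, -0.727 to -0.363 and -0.189 to 0.258 in CD8 cells, changing sign at 0.176, 0.006 and 0.258 without Cd4CreTet2KO replicates 1 and 4 and Vav1CreTet2KO replicate 3. In CD4 cells it ranged over -0.343 to 0.154, -0.031 to 0.572 and -0.595 to -0.127, changing sign at 0.154 and 0.035 without Tet2fl/fl replicate 2 and Vav1CreTet2KO replicate 3, and at -0.031 without Cd4CreTet2KO replicate 2.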

Other observations

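The tests of an explanation and the dendritic cell marker lists in this part were chosen after the results were seen, and the splits of the libraries were planned.

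Plasmacytoid dendritic cells, the main makers of type I interferon, and conventional type 1 dendritic cells, which take up dead cells for cross-presentation, were looked at through added marker lists, which share 5 genes with the planned dendritic cell list. In CD8 Vav1CreTet2KO libraries 6 of 17 plasmacytoid markers rose (limma adjusted p under 0.05, median log2 fold change 2.44) and 3 of 15 conventional type 1 markers rose (median 1.78). In CD8 Cd4CreTet2KO libraries 1 of 17 and 0 of 15 rose, with medians of 1.89 and 1.40. On recovered reads with TMM scaling 4 of 17 and 1 of 15 rose in Vav1CreTet2KO (medians 3.37 and 2.33). There 3 of 17 and 1 of 15 rose in Cd4CreTet2KO (medians 3.29 and 2.33). In CD4 cells, whose folds come from counts, none passed in edgeR's test, with medians of 1.70 and 0.88 in Vav1CreTet2KO and 0.36 and -0.09 in Cd4CreTet2KO. The type I interferon list was higher in the CD8 comparisons with the largest plasmacytoid medians, at 0.94 and 0.67, but with camera adjusted p = 0.557 and 0.232 at an estimated correlation and no member past the test by itself. Both lists hold Bst2, and the plasmacytoid list was chosen after rising genes were seen, so the lists are not independent.

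Tox, Tox2, Cd200r1 and Ikzf2 had medians of -2.13 and -1.81 in CD8 Vav1CreTet2KO and Cd4CreTet2KO cells. Scaling of RPKM was excluded as the cause, since their median on recovered reads with TMM scaling was -1.79 or lower in both. Fewer T cells per library were excluded as the whole cause, since 12 invariant T cell genes had medians of -0.02 and -0.32. These 12 ranged from -1.31 to 0.61 and from -1.16 to 0.14, with 6 and 2 of them above 0. Among them Zap70 fell in Vav1CreTet2KO, so a part played by fewer T cells was not excluded. Stress during tissue handling of the control libraries, which held more heat shock transcripts in both cell types, may be a further cause and stays open: the same genes had medians of -0.93 and 0.08 in CD4 Vav1CreTet2KO and Cd4CreTet2KO cells, where heat shock genes had medians of -0.62 and -0.84. The loss of Tet2, which the design names, stays among the open explanations.

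With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 148 genes and 11 lists for CD8 Vav1CreTet2KO, against at most 1 and 8 in the others, and as many or more came from 1 of 10 splits for genes and 1 of 10 for lists, the real one included. In CD4 cells the real and highest other counts of genes were 1 and 0 for Vav1CreTet2KO, 4 and 0 for Cd4CreTet2KO and 9 and 0 between them, and those of lists 8 and 9, 6 and 7, and 12 and 8. As many lists came from 3, 3 and 1 of the 10 splits and as many genes from 1 of 10 in each. For CD8 Cd4CreTet2KO 1 of 35 splits gave 52 genes or more, against 1 gene in the highest other split, so chance was excluded at this share, but 4 of 35 gave 16 lists or more (highest other 18), so chance was not excluded for the lists. Between the CD8 knockouts 8 of 35 splits gave 8 lists or more (highest other 11), so chance was not excluded for the lists. The counts of genes between the CD8 knockouts and for the interaction of Vav1CreTet2KO were 0, which all 35 and all 100 splits reach by construction, so these splits decide nothing. The highest other counts were 8 and 706. The split with 706 exchanged the genotypes in CD4 cells alone, so that the effects of the cell types were summed, in a fit without a block for the animals they share. It points to a structure of the samples, whose cause was not tested.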
